A study of Mus musculus with 12 samples.

How the data were processed

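The samples were WAT and BAT of male mice aged 20 weeks, Per2-/- or per2+/+, 3 biological replicates per group and 1 Affymetrix array per replicate (12 arrays, 4 groups). Per the labels, each array was 1-colour. The intensity values deposited by the authors are linear PLIER values; the version of PLIER and any scaling between arrays are not given in the sources used here. In 4 comparison tables the authors ran Cyber-T (8.01, with hdarray 3.71 in R 2.2.1), and per the file headers each deposited p-value comes from a regularized t test, once on linear values and once on natural logs, without adjustment for multiple tests. The deposited score of the authors is a signed fold of linear group means. The intensity values repeated in those tables, 173550 per table, were checked against the main value table and differed by no more than 0.06 plus 1e-04 of the value, compared in sorted order within each group of arrays. The arrays' median intensities were 71.4, 69.7, 57.9 and 59.1 on average in WAT of WT, WAT of KO, BAT of WT and BAT of KO; an intensity array has no read depth, and with 3 arrays per group the median SE of a log2 difference was 0.127.

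The value table held 35557 transcripts, of which the authors tested 28925. Gene names came from a table that names 23410 transcripts; 21789 of them name 1 gene and 1621 several, and 12147 transcripts have no listed gene. Only transcripts tested by the authors and naming 1 gene were used, and for each gene the transcript with the highest mean, giving 19933 genes. The plan had been to leave out control transcripts, which the files do not mark, and the authors' choice of tested transcripts took its place once the tables had been read. Of the transcripts naming 1 gene, 21698 were matched by gene identifier and 91 were not; 0 symbols needed updating, and 696 tested transcripts share all their values with another. The genome build of the array design is not given in the sources used here, so no coordinates are reported; gene order for 1 test of neighbouring genes came from assembly GRCm38.p6.

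Values were transformed as log2(intensity + 16) and fitted with limma 3.58.1 in R 4.3.3, with 4 group means, 8 residual and 3.51 prior degrees of freedom, and no trend. Because 16 was added, folds of dim genes are smaller than the ratio of their means. The 5 comparisons were KO minus WT in WAT and in BAT, BAT minus WAT in WT and in KO, and the difference of the 2 genotype differences (BAT minus WAT). P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Whether arrays of 2 groups overlapped was also counted; for 3 against 3 arrays chance gives 10%.

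The groups of genes were 24 lists written from general knowledge: genes driven by E-box and D-box elements, positive-limb and RORE-driven clock genes, brown-fat thermogenic genes, white adipocyte genes, adipocyte genes downstream of PPARγ, de novo lipogenesis, cholesterol synthesis, fatty acid oxidation, respiratory chain, TCA cycle, macrophage, lymphocyte, skeletal muscle, epididymis and testis, mesothelium, endothelium, fibroblast matrix, Schwann cell and nerve, erythroid, immediate early stress, interferon response, cell cycle, glucocorticoid response and ribosomal protein genes. They hold 480 memberships of 477 genes, of which 426 were measured; 3 genes stand in several lists, and measured lists have 4 to 50 members. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation and with limma's fry. Members were also adjusted over their list alone.

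Genes are named by a rule: Per2; in each comparison the 6 called genes with the largest rise and the 6 with the largest fall whose arrays did not overlap (for the difference of differences, by adjusted p alone); and in each list up to 2 members with the smallest p under 0.05 before adjustment. Further called members and members that were not called are given as examples of their list, and other genes are stated to have been chosen after their values were seen. The groups, comparisons, lists, naming rule and all alternatives but 2 were set before the data were examined. The alternatives were other added constants (1 and 64), quantile normalization, median centring, fitting only the 6 arrays compared, a mean-variance trend with robust variances, array weights, the replicate number as a fixed block, genotype with replicate number as a random block, brighter genes only, only genes differing between the tissues (for the correlation), all transcripts the authors tested, the authors' p-values, an unadjusted p under 0.05 with at least 1.5-fold, and leaving out each array. Added afterwards were the subtraction of BAT signal from the WAT arrays of KO and a count among genes differing under 2-fold between the tissues.

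The procedure was tested on simulated data with the residual spread of each gene in the 12 arrays, for the WAT comparison. Of 50 genes changed by 0.5, 1, 2 or 4 on the log2 scale, limma called 20, 39, 50 and 50, with 8 unchanged genes called. A list shifted by 0.5 passed camera with an adjusted p of 3.02e-16 while 0 other lists did. The simulated errors were independent between genes, so the list result does not cover lists whose genes vary together. For the correlation of 2 differences that share arrays, 100 simulations without change were run with the same spread. They gave the r and covariance that sharing would produce at that spread where the tissues do not differ. Not analysed here were raw scans and transcripts without a single gene name except for 1 count. No pairing of WAT with BAT entered the 5 comparisons, since the labels do not state that they came from the same animals. The replicate number linked arrays only in the 2 block alternatives, in a check of pairings, in 1 set of shares of the distance to BAT and in the subtraction, which took the BAT array of the same number.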

Results

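RNA was measured on 1-colour Affymetrix arrays in white adipose tissue (WAT) and brown adipose tissue (BAT) of male mice aged 20 weeks, either lacking Per2 (Per2-/-, here KO) or carrying the intact gene (per2+/+, here WT). Per2 encodes a repressor of the circadian clock. Each of the 4 groups held 3 arrays, described as biological replicates, 12 arrays in all. The labels do not say whether the WAT and BAT samples of a given number came from the same animal. The median intensity over the measured transcripts was 71.4 ± 0.976 (mean ± SD, n = 3) in WAT of WT, 69.7 ± 4.18 in WAT of KO, 57.9 ± 2.14 in BAT of WT and 59.1 ± 0.586 in BAT of KO. Intensities below are means ± SD of 3 arrays in PLIER units, and the number of arrays limits their precision. Rank correlations between WT WAT arrays were 0.989 to 0.992. WAT of KO replicate 3 stood apart: its correlation with the other 2 KO arrays was 0.954 and 0.956, and with the BAT arrays it was 0.886 to 0.897, against 0.806 to 0.837 for the other WAT arrays.

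Per2 transcript itself was present in every group and was not called different between the genotypes. In WAT its intensity was 112 ± 11.4 in WT and 132 ± 35.0 in KO (log2 difference 0.19, SE 0.14, adjusted p = 0.615). In BAT it was 165 ± 8.22 in WT and 149 ± 9.85 in KO (log2 difference -0.14, SE 0.14, adjusted p = 0.773). The position of the Per2 probes relative to the deleted part of the gene is not given in the sources used here, so these values do not check the genotype labels.

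The comparison of KO with WT in WAT asked what differed with the loss of Per2 in white fat. Genes of brown fat were among those that rose most. Ucp1, the uncoupling protein of brown-fat mitochondria, went from 6.05 ± 1.17 in WT to 3222 ± 1064 in KO (log2 difference 7.15, SE 0.17, adjusted p = 1.05e-09). Cidea, a lipid-droplet protein abundant in brown fat, went from 10.3 ± 1.98 to 1329 ± 428 (log2 difference 5.63, SE 0.17, adjusted p = 7.43e-09). Cox8b, a cytochrome oxidase subunit, rose 17.5-fold (SE of the log2 difference 0.24) and Fabp3, a fatty acid carrier, rose 16.1-fold (SE 0.21). Of the 21 measured members of the brown-fat thermogenic list, 14 rose by limma, none fell and 7 were not called; adjusted over the list alone 16 rose, and the authors' p-values called 15 and 14 on log and linear values. Dio2, which activates thyroid hormone, rose by a log2 difference of 2.27 (adjusted p = 0.00269), Elovl3, a fatty acid elongase, by 3.89 (2.1e-05) and Ppara by 1.08 (0.00992). The transcriptional regulators Ppargc1a (0.30, adjusted p = 0.631) and Prdm16 (0.05, adjusted p = 0.934) were not called. The list's median log2 difference was 1.61, and it passed camera with an adjusted p of 1.05e-36; adjusted p = 0.0257 with an estimated correlation. Intensities in BAT of WT were higher still, at 10796 ± 356 for Ucp1 and 6203 ± 260.5 for Cidea. Skeletal muscle genes also had positive differences in WAT of KO, with 18 of 22 members above all 3 WT arrays and a median log2 difference of 0.87. Limma called only 1 of the 22, and the list did not pass camera with an estimated correlation (adjusted p = 0.38). Of all 19933 genes, 4096 did not overlap between the genotypes in either direction.

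Genes of mitochondrial fuel use moved up in the same arrays. In fatty acid oxidation 17 of 23 measured members rose (18 adjusted over the list alone), in the TCA cycle 12 of 15 (15) and in the respiratory chain 10 of 50 (41), and no member of these lists fell. From the authors' p-values the counts were 16, 10 and 5 on log values and 7, 3 and 0 on linear values. Pdk4, which inhibits pyruvate dehydrogenase, went from 79.3 ± 10.5 to 832 ± 317 (log2 difference 3.10, SE 0.19, adjusted p = 3.95e-06). Hadhb, of the mitochondrial trifunctional protein, rose 3.63-fold (log2 difference 1.86, SE 0.16, adjusted p = 5.33e-05). The succinyl-CoA ligase subunits Suclg1 and Sucla2 rose 2.25-fold (log2 difference 1.17, SE 0.13, adjusted p = 0.000659) and 2.58-fold (log2 difference 1.37, SE 0.17, adjusted p = 0.000901). Cox5a rose 1.77-fold (0.00699) and Ndufs1 of complex I 1.94-fold (0.00992). The median log2 differences were 0.93, 0.88 and 0.45, with camera adjusted p of 5.08e-28, 7.73e-23 and 5.08e-28. With an estimated correlation none of the 3 passed: adjusted p = 0.159, 0.159 and 0.295. The skeletal muscle list was higher in the same KO arrays, with median intensities of 37.7, 109 and 77.7 against 13.1 to 15.9 in WT.

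Lists of adipocyte genes showed smaller differences. Of 25 measured adipocyte genes downstream of PPARγ, 3 rose by limma, none fell and 22 were not called (3 and 0 called from the authors' p-values on log and linear values; adjusted over the list alone 5 rose and 1 fell; median 0.43, camera adjusted p = 8.08e-08, adjusted p = 0.38 with an estimated correlation). The called ones were Cebpb, an adipogenic transcription factor (274 ± 18.2 to 466 ± 115, adjusted p = 0.0196), Gpd1, a glycerol phosphate dehydrogenase (1544 ± 106 to 3312 ± 1361, adjusted p = 0.0206), and Pck1 (0.99 on the log2 scale, adjusted p = 0.0478). The rise of this list lay mostly on KO replicate 3: its mean log2 level was 11.48 there, 10.51 and 10.52 on the other KO arrays, and 10.33 to 10.47 in WT. Among 18 genes of de novo lipogenesis, Acacb (2.44-fold, adjusted p = 0.0146) and Fasn (1.64-fold, adjusted p = 0.044) rose and none fell (4 rose adjusted over the list alone; list median 0.21, camera adjusted p = 0.00385, adjusted p = 0.38 with an estimated correlation). Pparg itself was 830.5 ± 46.3 in WT and 1225 ± 693 in KO (0.42, adjusted p = 0.537). None of 14 white adipocyte genes was called by limma at the adjusted threshold, 2 had an unadjusted p under 0.05, and 0 were called from the authors' p-values; their median log2 difference was 0.12 but their mean was -0.00 (camera adjusted p = 0.904). Their mean log2 level was 9.19 on KO replicate 3 but 8.58 and 8.65 on the other KO arrays, against 8.80 to 8.82 in WT. The mean difference thus joins KO arrays on both sides of WT. Leptin was 866 ± 119 in WT and 1084 ± 702 in KO. In skeletal muscle Myh4, a fast myosin, rose from 2.76 ± 1.26 to 114 ± 65.3 (log2 difference 2.64, SE 0.53, adjusted p = 0.0223). Limma did not call the other 21 of 22 members, 6 rose adjusted over the list alone, and the authors' p-values after the same adjustment called 15 on log and 14 on linear values (camera adjusted p = 1.21e-07; adjusted p = 0.38 with an estimated correlation). Of 14 glucocorticoid-responsive genes only Pdk4 rose (2 adjusted over the list alone; camera adjusted p = 0.0331, adjusted p = 0.38 with an estimated correlation). The 16 endothelial genes all had positive differences with a median of 0.21, 0 of them called by limma and 2 with an unadjusted p under 0.05, and 0 from the authors' p-values (camera adjusted p = 0.0026, adjusted p = 0.556 with an estimated correlation). Their mean log2 level was 8.37 on KO replicate 3 but 7.49 and 7.60 on the other KO arrays, against 7.55 to 7.64 in WT.

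The genes that fell most in WAT of KO belonged to none of these groups. Klrb1c, a natural killer cell receptor, went from 525 ± 70.4 to 9.61 ± 7.87 (log2 difference -4.44, SE 0.19, adjusted p = 1.51e-07), and Scube1 from 1431 ± 256 to 54.3 ± 22.5 (log2 difference -4.39, SE 0.19, adjusted p = 1.51e-07). AI506816 fell by 4.17, Gm609 by 4.10, 9230020A06Rik by 3.24 and Rarres1 by 3.23 on the log2 scale. The other genes that rose most were BC018473, from 3.60 ± 6.13 to 2021 ± 1274 (log2 difference 6.44, SE 0.48, adjusted p = 2.1e-05), and Gdpd3, from 15.1 ± 0.798 to 558 ± 172 (log2 difference 4.17, SE 0.17, adjusted p = 1.51e-07). Among 18 matrix genes 3 fell, the collagens Col1a1 (3379 ± 1245 to 1156 ± 72.5, adjusted p = 0.00578) and Col1a2 (0.0414) and the matrix protein Sparc (0.0494). None rose (5 fell adjusted over the list alone; median -0.44, camera adjusted p = 1.23e-05, adjusted p = 0.38 with an estimated correlation). Among 19 cell cycle genes 3 fell and none rose (8 fell adjusted over the list alone): Top2a (-0.80, adjusted p = 0.0274), Cdk1 (-0.72, adjusted p = 0.0378) and Aurkb (-0.52, adjusted p = 0.0405). The list median was -0.48 and the camera adjusted p 1.08e-08; adjusted p = 0.159 with an estimated correlation. Cyp51, of sterol synthesis, was the 1 of 19 cholesterol genes that fell (-0.78, adjusted p = 0.0414; 1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.00385, adjusted p = 0.38 with an estimated correlation). Oasl2 was the 1 of 18 interferon-response genes that fell (-0.62, adjusted p = 0.0322; 4 adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.38 with an estimated correlation).

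All 23 ribosomal protein genes had negative differences in WAT of KO (median -0.24), with 0 called by limma, 11 at an unadjusted p under 0.05 and 0 from the authors' p-values (camera adjusted p = 1.21e-07, adjusted p = 0.38 with an estimated correlation). All 14 epididymis and testis genes were lower too (median -0.55), with 0 called by limma, 4 at an unadjusted p under 0.05, and 1 and 2 from the authors' p-values on log and linear values. Camera gave an adjusted p of 0.000829; adjusted p = 0.409 with an estimated correlation. Without KO replicate 3, whose epididymal intensities were the lowest, the latter list no longer passed (adjusted p = 0.465; range over its alternatives 2.72e-05 to 0.465). Clock genes were not called in WAT. No time of day entered the comparisons, so a difference in the phase or amplitude of a rhythm was not tested in either tissue. Of 11 measured genes driven by E-box and D-box elements and of 5 positive-limb and RORE-driven genes, limma called 0, and 2 of each had an unadjusted p under 0.05 (camera adjusted p = 0.425 and 0.805; 0 from the authors' p-values). Per1 was 203 ± 11.8 in WT and 299 ± 98.4 in KO (log2 difference 0.48, SE 0.18, adjusted p = 0.241), Nfil3 differed by 0.52 (adjusted p = 0.241), Bhlhe40 by -0.50 (0.354) and Arntl by -0.58 (0.263). Macrophage (0.863), lymphocyte (0.884), Schwann cell and nerve (0.175), erythroid (0.495), immediate early (0.428) and mesothelial genes (0.978) did not pass camera, adjusted p in parentheses. Limma called 0 members of the first 5; 1, 2, 3, 1 and 1 had an unadjusted p under 0.05, and the authors' p-values on linear values called 1 lymphocyte and 1 immediate early gene. The lymphocyte median was 0.03 and its mean -0.01 (camera up). Among the mesothelial genes Upk1b fell (-0.82, adjusted p = 0.0223), and the list's median of 0.20 and its mean of -0.09 had opposite signs, as had the directions given by camera and by fry.

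**Figure D1:**
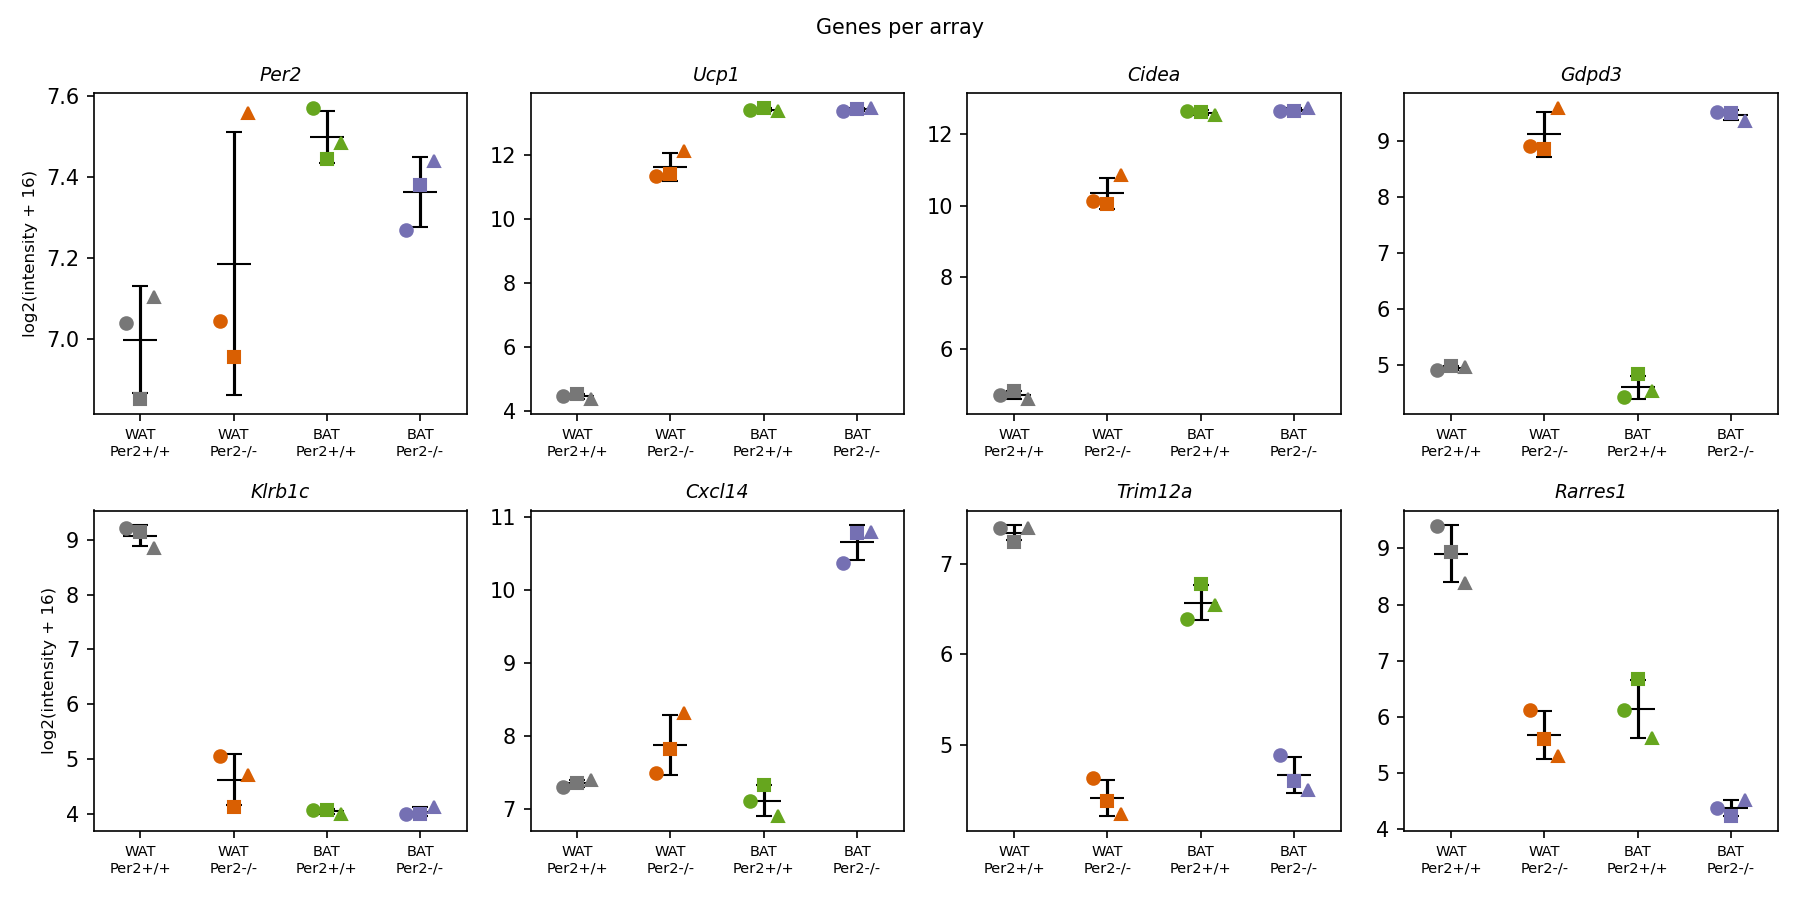
Log2(intensity + 16) of single genes (vertical axis) in the 4 groups (horizontal axis); each point is an array, its shape gives the replicate number, and bars are the mean ± SD of 3 arrays. Ucp1 intensities were 4.76 to 7.05 in WAT of WT, 2554 to 4449 in WAT of KO and 10433 to 11144 in BAT.

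In total 482 of 19933 genes passed limma at an adjusted p under 0.05 in WAT, 253 higher and 229 lower in KO, with 86 and 69 of them beyond 2-fold; 2767 had an unadjusted p under 0.05. In all 482 the KO and WT arrays did not overlap, as was so for 4096 of all genes, where chance gives 10% for 3 against 3 arrays. Of the 24 lists 15 passed camera, 9 up and 6 down, 5 passed fry, and 1, the brown-fat list, held with an estimated correlation. Leaving out KO replicate 3 gave 871 genes, and leaving out WT replicate 1, 2 or 3 gave 316, 254 or 225. With KO replicate 3 out, the calls of the PPARγ adipocyte (adjusted p = 0.0563), lipogenesis (0.165), endothelial (0.426) and glucocorticoid (0.254) lists also ended, and the endothelial median turned to -0.07. The glucocorticoid list also failed without WT replicate 3 (0.117) and among the brighter genes (0.128, where the cell cycle list had 0.061), over a range of 0.0117 to 0.38. With BAT signal subtracted the muscle (0.542) and lipogenesis (0.265) lists failed. The subtracted shares were set from the muscle genes, so the loss of the muscle list and the drop of Myh4 were built in. Fitting the 6 WAT arrays alone gave 127 genes and subtracting BAT signal from the WAT arrays of KO gave 255 (93 higher and 162 lower, with 92 of the 253 rises and 153 of the 229 falls kept), and both ended the calls of Cebpb, Gpd1, Acacb, Fasn, Cox5a, Ndufs1, Cyp51, Myh4, Upk1b, Col1a2, Oasl2, Top2a and Cdk1. The fit of 6 arrays also ended the calls of Sucla2 (adjusted p = 0.0528) and Col1a1 (0.0737); it left the differences as they were and changed only the spread and its degrees of freedom. The subtraction lowered the differences of Cebpb from 0.71 to 0.21, Acacb from 1.28 to 0.77, Cox5a from 0.82 to 0.39, Ndufs1 from 0.96 to 0.52, Gpd1 from 1.02 to 0.73 and Myh4 from 2.64 to 0.69. It moved the others less, with Fasn from 0.71 to 0.62, Upk1b from -0.82 to -0.69, Col1a2 from -1.01 to -0.93, Oasl2 from -0.62 to -0.55, Top2a from -0.80 to -0.73, Cyp51 from -0.78 to -0.81 and Cdk1 from -0.72 to -0.73. Their adjusted p after it were 0.0624 to 0.135. The authors' p-values gave 261 higher and 275 lower genes on log values and 167 and 370 on linear values. Among brown-fat genes the subtraction ended 4 of 14 calls: Dio2 (from 2.27 to 0.38, adjusted p = 0.718), Ppara (from 1.08 to 0.14, 0.851), Slc27a2 (from 1.45 to 0.03, 0.977) and Acot11 (from 2.63 to 0.995, 0.12). Other alternatives ended calls too: Oasl2 passed in 7 and Top2a in 9 of 17, Col1a2 and Upk1b in 10 and Fasn and Myh4 in 11 of 18, Cyp51 and Cdk1 in 11 of 19, and of 18 Gpd1 in 13, Cebpb and Acacb in 14, Cox5a and Ndufs1 in 16 and Sucla2 and Col1a1 in 17. Pck1, Sparc and Aurkb were not followed over the alternatives.

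**Figure D2:**
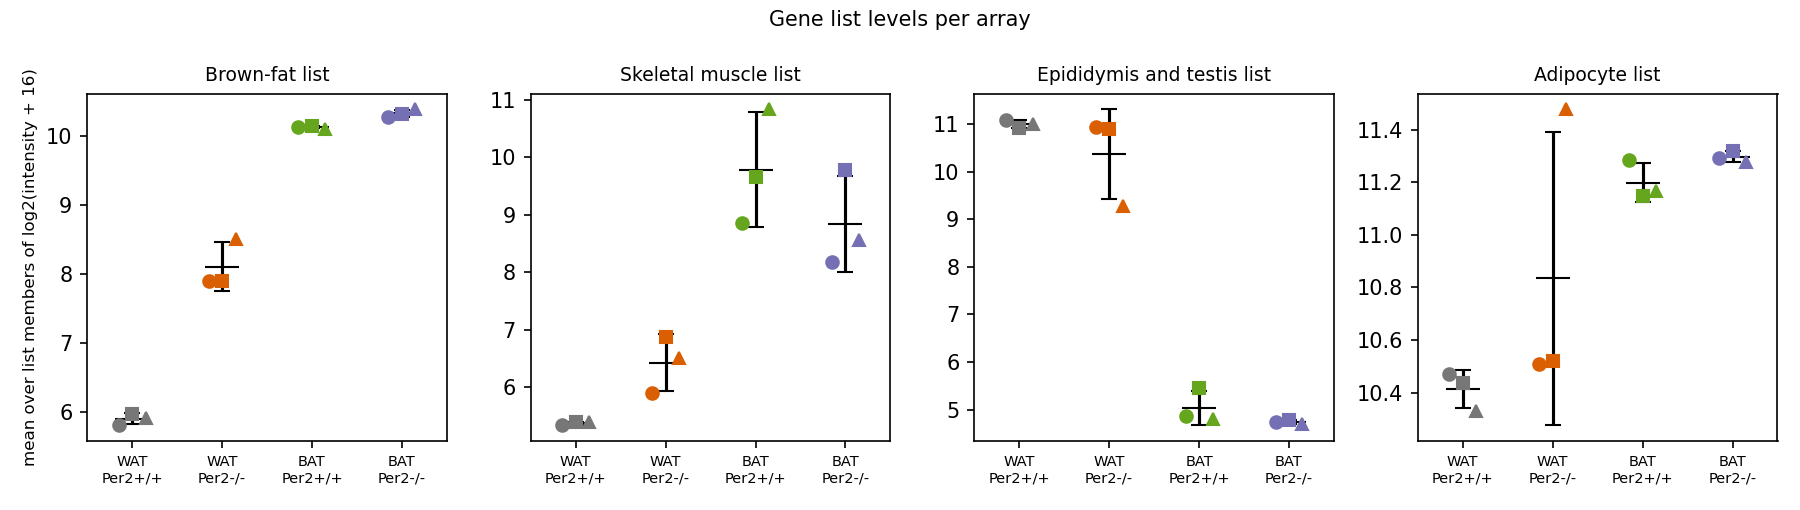
Mean log2(intensity + 16) over the members of a gene list (vertical axis) in the 4 groups (horizontal axis); each point is an array, its shape gives the replicate number, and bars are the mean ± SD of 3 arrays. The brown-fat list lay at 5.81 to 5.97 in WAT of WT, 7.89 to 8.51 in WAT of KO and 10.11 to 10.39 in BAT.

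In BAT, where the same comparison asked what differed with the loss of Per2 in brown fat, Gdpd3, a glycerophosphodiester phosphodiesterase, rose most, from 8.60 ± 3.64 in WT to 692 ± 42.3 in KO (log2 difference 4.86, SE 0.17, adjusted p = 5.66e-08). The chemokine Cxcl14 went from 123 ± 20.2 to 1608 ± 255 (log2 difference 3.54, SE 0.19, adjusted p = 3.19e-06) and Abhd1 from 72.9 ± 12.0 to 961 ± 71.8 (log2 difference 3.46, SE 0.12, adjusted p = 5.66e-08). Fbp1, a gluconeogenic phosphatase, rose 6.43-fold (SE of the log2 difference 0.21), Gchfr, which regulates GTP cyclohydrolase, 8.01-fold (SE 0.40) and BC018473 6.64-fold (SE 0.48). AI506816 (-2.68, adjusted p = 0.0205), the annexin Anxa8 (-2.01, adjusted p = 0.00558), Nxpe4 (-2.01, adjusted p = 0.00891), Rab6b (-1.91, adjusted p = 0.00522), Trim12a (-1.90, adjusted p = 5.17e-05) and Cish, an inhibitor of cytokine signalling (-1.87, adjusted p = 0.0114), fell most on the log2 scale. Ucp1 was 10796 ± 356 in WT and 10864 ± 310.4 in KO (log2 difference 0.01, SE 0.17, adjusted p = 0.993).

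Interferon-response genes were the list with the most calls in BAT: of 18 measured members 4 fell by limma, none rose and 14 were not called, and 8 fell adjusted over the list alone (5 called from the authors' p-values). Rsad2, an antiviral enzyme, fell 2.24-fold (log2 difference -1.16, SE 0.10, adjusted p = 9.32e-05), Rtp4 from 190.1 ± 27.2 to 71.8 ± 18.1 (adjusted p = 0.00906), the antiviral tether Bst2 by a log2 difference of -0.88 (0.0346) and the transcription factor Irf7 by -0.67 (0.0275). The list median was -0.37, with a camera adjusted p of 7.74e-10, a fry adjusted p of 0.0125, and adjusted p = 0.15 with an estimated correlation. Skeletal muscle genes were lower in BAT of KO (median -0.96, camera adjusted p = 8.92e-09), although limma called 0 of 22 (8 at an unadjusted p under 0.05; 5 and 1 from the authors' p-values on log and linear values) and the estimated correlation gave an adjusted p of 0.875. Their spread between arrays was wide: Myh4 was 2263 ± 1655 in WT and 1171 ± 710.1 in KO. Matrix genes had a median of -0.41, 17 of 18 negative, with 0 called by limma, 6 at an unadjusted p under 0.05 and 8 from the authors' p-values (camera adjusted p = 5.19e-06, adjusted p = 0.875 with an estimated correlation). Col1a1 was 966 ± 227 in WT and 483 ± 72.0 in KO (adjusted p = 0.0686). Respiratory chain (-0.09) and ribosomal protein (-0.09) medians were slightly negative (camera adjusted p = 0.00101 and 0.00181; adjusted p = 0.875 for both with an estimated correlation). Limma called 0 in each, 4 and 1 members had an unadjusted p under 0.05, and the authors' p-values on log values gave 6 and 0.

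Brown-fat genes in BAT did not pass as a list (camera adjusted p = 0.127). Slc27a2, a fatty acid transporter, rose from 1822 ± 133 to 2546 ± 168 (adjusted p = 0.0296) and limma did not call the other 20 of 21 members (2 rose adjusted over the list alone; 5 and 6 were called from the authors' p-values on log and linear values). Elovl3 was 942 ± 142 in WT and 2300.0 ± 489 in KO (adjusted p = 0.0561). Gadd45b (-1.45, adjusted p = 0.00793) and Ier3 (-0.89, adjusted p = 0.0101), both stress-induced, fell among 19 immediate early genes (2 adjusted over the list alone; list adjusted p = 0.194). Sc5d, of sterol synthesis, fell among 19 cholesterol genes (-0.79, adjusted p = 0.0221; 1 adjusted over the list alone; list adjusted p = 0.582). In the 2 clock lists limma called 0 of 11 and 0 of 5 members, 2 and 1 had an unadjusted p under 0.05, and the authors' p-values on log values called 3 and 1. Adjusted over the list alone 1 rose and 1 fell in the first and 1 rose in the second (camera adjusted p = 0.194 and 0.773). Per1 was 194 ± 27.5 in WT and 296 ± 25.4 in KO (log2 difference 0.58, SE 0.18, adjusted p = 0.171), Nfil3 differed by 0.63 (adjusted p = 0.166) and Bhlhe40 by -0.75 (0.159). Camera adjusted p was 0.0978 for glucocorticoid, 0.0972 for epididymis, 0.133 for fatty acid oxidation, 0.194 for TCA cycle, lipogenesis, erythroid and cell cycle, and 0.334 for endothelial genes. It was 0.518 for white adipocyte and PPARγ adipocyte, 0.769 for Schwann cell, 0.773 for macrophage and lymphocyte and 0.827 for mesothelial genes. Limma called 0 members of these 14 lists, while the authors' p-values on log values called 5 glucocorticoid, 5 white adipocyte, 5 PPARγ adipocyte, 4 lipogenesis and 4 fatty acid oxidation genes and at most 1 in each other list. Several lists in BAT differed in sign between their measures. White adipocyte genes had a median of -0.00 and a mean of 0.19 (camera up), immediate early genes 0.00 and -0.06 (camera down), Schwann cell genes -0.01 and 0.00 (camera down), and mesothelial genes 0.01 and 0.05 (camera down, fry up).

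Across BAT 343 genes passed limma, 181 higher and 162 lower in KO, 49 and 38 of them beyond 2-fold, and 2491 had an unadjusted p under 0.05. The arrays of the 2 genotypes did not overlap in any of the 343, nor in 4477 of all genes (10% by chance). Of the lists 5 passed camera, all down, 1 passed fry and 0 held with an estimated correlation. The authors' p-values after the same adjustment gave 1071 genes on log values and 1067 on linear values; leaving out WT replicate 2 or 3 gave 219 or 223 genes, and KO replicate 1, 2 or 3 gave 185, 179 or 165. The ribosomal protein list failed without WT replicate 2 (adjusted p = 0.146, range over its alternatives 8.46e-05 to 0.875). The calls of BC018473, AI506816, Slc27a2 and Sc5d ended in at least 4 of the 6 omissions of a BAT array, and those of Nxpe4 (KO replicate 3), Cish (WT replicate 1) and Rtp4 (KO replicate 1 or 3) in 1 or 2. Over all alternatives the highest adjusted p of these 7 genes were 0.128, 0.0955, 0.132, 0.106, 0.0514, 0.0529 and 0.0531.

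Some genes changed in the same direction in both tissues. Of 83 genes called in WAT and in BAT, 80 went the same way, 42 up and 38 down, where independent calls would give 2.30 and 1.86. For 7 of the 80 the size of the difference was itself unequal between the tissues, among them Abhd1 (adjusted p = 0.00227) and Trim12a (0.0425). Gdpd3 rose by 4.17 in WAT and 4.86 in BAT on the log2 scale, Abhd1 by 1.99 and 3.46, Hal, histidine ammonia-lyase, by 2.85 and 2.13, Rbp7, a retinol-binding protein, by 2.62 and 2.64, and Gbp2b, a guanylate-binding protein, by 2.54 and 2.29. Trim12a (-2.93 and -1.90), Rarres1 (-3.23 and -1.75) and AI506816 (-4.17 and -2.68) had negative differences in both tissues, as had Mcm6, of the replicative helicase (-1.08 and -1.25). Haus4 (-1.60 in WAT, 1.23 in BAT), Lrrc23 (-0.85, 0.55) and Cmbl (0.63, -0.64) went opposite ways. Hal, Rbp7, Gbp2b, Mcm6, Haus4, Lrrc23 and Cmbl were chosen after their values were seen. Across all genes, which are not independent replicates, the 2 genotype differences correlated with r = 0.258.

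**Figure D3:**
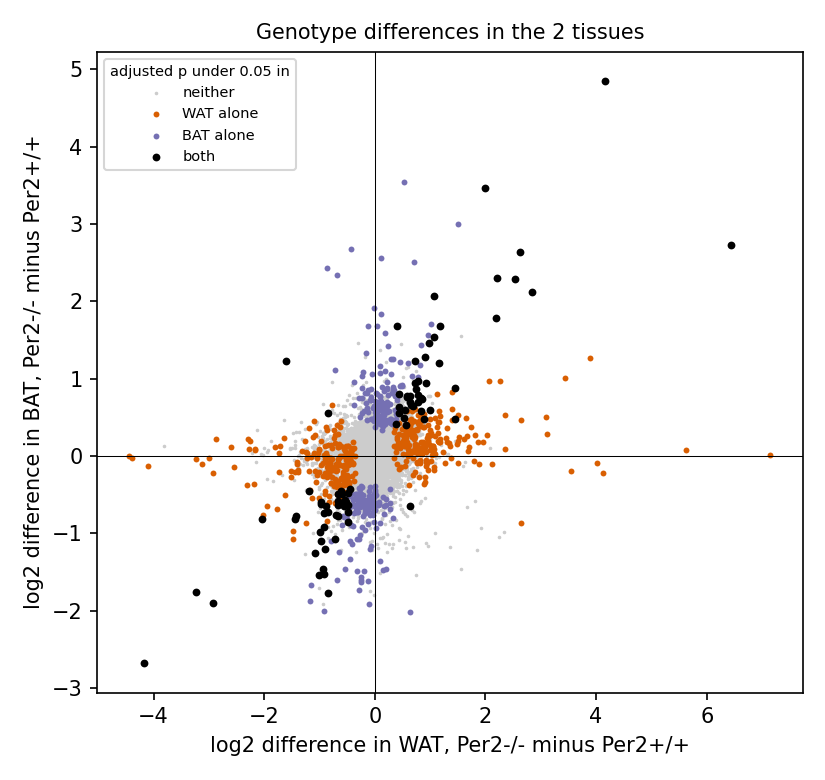
Log2 difference KO minus WT in WAT (horizontal) and in BAT (vertical); each point is a gene. Genes called in both tissues lie mostly in the quadrants where both differences have the same sign (80 of 83).

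The difference of the genotype differences asked whether the genotype difference was unequal in the 2 tissues. The brown-fat genes gave the largest negative values: Ucp1 differed by -7.14 (SE 0.24, adjusted p = 5.6e-08), Cidea by -5.56 (4.42e-07), Cox8b by -4.36 (5.27e-05), Fabp3 by -4.10 (3.47e-05) and Cox7a1 by -3.73 (1.2e-05), negative because the gain was in WAT. Of 21 brown-fat members 12 passed, all negative (15 adjusted over the list alone; camera adjusted p = 3.88e-34, adjusted p = 0.0332 with an estimated correlation). At the other end stood Klrb1c (4.44), Scube1 (4.37), Gm609 (3.97), 9230020A06Rik (3.20) and Krt23, a keratin (3.09), which were lower in WAT of KO, and Fbp1 (3.12), which rose in BAT. BC018473 gave -3.71 (adjusted p = 0.0347). Fatty acid oxidation had 6 negative calls of 23 members (17 adjusted over the list alone), the TCA cycle 2 of 15 (11) and the respiratory chain 0 of 50 by limma (39 alone, 41 at an unadjusted p under 0.05). Their camera adjusted p were 4.26e-21, 1.96e-17 and 1.47e-34; with an estimated correlation the adjusted p was 0.247 for each. Skeletal muscle genes, whose median genotype difference was 0.87 in WAT and -0.96 in BAT, had a median of -1.97 here (camera adjusted p = 1.07e-17, adjusted p = 0.265 with an estimated correlation). Limma called 0 of 22 muscle genes, 16 had an unadjusted p under 0.05 and 12 passed adjusted over the list alone, all negative.

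Smaller differences between the tissues' responses came from the PPARγ adipocyte (-0.31), endothelial (-0.25) and interferon (-0.20) lists, with negative medians, and from the cholesterol (0.28) and cell cycle (0.36) lists, with positive ones. Their camera adjusted p were 7.45e-05, 0.000893, 0.00559, 0.00648 and 0.00018; with an estimated correlation adjusted p = 0.585 for the first 2, 0.421 for the next 2 and 0.415 for cell cycle. Rsad2 was the 1 interferon gene called (log2 difference -1.08, SE 0.14, adjusted p = 0.00378); in the other 4 lists limma called 0, and 2, 1, 7 and 7 members had an unadjusted p under 0.05. Pdk4 (-2.59, adjusted p = 0.00102), Hadhb (-1.68, adjusted p = 0.00516), Sucla2 (-1.39, adjusted p = 0.0227), Cxcl14 (3.02, adjusted p = 0.000248) and Anxa8 (-2.64, adjusted p = 0.0177) also differed. Camera adjusted p was 0.0578 and 0.972 for the clock lists, 0.0542 for immediate early, 0.074 for erythroid and ribosomal protein, 0.138 for Schwann cell, 0.173 for lipogenesis, and 0.274 for epididymis genes. It was 0.598 for white adipocyte, 0.613 for glucocorticoid, 0.651 for macrophage, 0.804 for matrix and 0.945 for lymphocyte and mesothelial genes. Median and mean differed in sign for the positive-limb clock (-0.06 and 0.09), mesothelial (-0.12 and 0.14) and glucocorticoid genes (0.07 and -0.12), camera giving down for each.

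Between the tissues' responses 118 genes differed, 63 positive and 55 negative, and 1887 had an unadjusted p under 0.05. Of the lists 10 passed camera, 2 up and 8 down, 1 passed fry and 1, the brown-fat list, held with an estimated correlation. The count was 372 without WAT KO replicate 3, and 73, 71 and 59 without WAT WT replicates 1, 2 and 3, 76 without BAT WT replicate 1 and 65, 59 and 68 without BAT KO replicates 1, 2 and 3. The calls of Krt23 and BC018473 ended in most alternatives (highest adjusted p 0.14 and 0.151), and without WAT KO replicate 3 so did those of the PPARγ adipocyte (adjusted p = 0.921) and endothelial lists (0.806). The interferon list failed without BAT WT replicate 3 (0.0559) and the cell cycle list among the brighter genes (0.221).

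The comparison of BAT with WAT in WT animals describes the tissues as sampled, and the WAT samples carried epididymal transcripts, given below. Which differences between the tissues, in either genotype, came from epididymis rather than fat was not tested. BAT had more Ucp1 (10796 ± 356 against 6.05 ± 1.17 in WAT, log2 difference 8.94, SE 0.17, adjusted p = 8.19e-11), Cidea (7.89, adjusted p = 1.58e-10), Fabp3 (7.11, adjusted p = 2.55e-09), Cox8b (7.03, adjusted p = 4.31e-09) and Cox7a1 (6.44, adjusted p = 1.02e-09). Of 21 brown-fat genes 20 were higher in BAT, as were 50 of 50 respiratory chain, 15 of 15 TCA cycle and 22 of 23 fatty acid oxidation genes. The exception in the last was Cpt1a (-2.66), the carnitine palmitoyltransferase of liver, and the counts adjusted over the list alone were the same. Their medians were 3.87, 2.08, 2.60 and 2.74, and camera gave adjusted p of 2.84e-18, 1.83e-32, 7.08e-14 and 9.22e-16; with an estimated correlation these were adjusted p = 0.101 for the first and 0.23 for the others. Skeletal muscle genes were higher in BAT too, 21 of 22, with Myh4 at 2263 ± 1655 against 2.76 ± 1.26 and Pvalb at 2355 ± 1797 against 13.9 ± 3.25 (list median 4.31, camera adjusted p = 4.43e-12, adjusted p = 0.23 with an estimated correlation).

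WAT of WT carried the transcripts of the epididymis at very high intensity. Defb48, a beta-defensin, was 47287 ± 4504 in WAT and 15.3 ± 6.09 in BAT (log2 difference -10.57, SE 0.48, adjusted p = 2.72e-08). Slc38a5, an amino acid transporter, was 215363 ± 17702 in WAT and 194 ± 9.13 in BAT (log2 difference -10.00, SE 0.40, adjusted p = 1.25e-08), and the epididymal lipocalin Lcn8 9930.1 ± 206 and 11.6 ± 10.6 (log2 difference -8.56, SE 0.40, adjusted p = 2.91e-08). Wfdc10 (-9.30, adjusted p = 5.06e-08), Teddm2 (-9.29, adjusted p = 3.8e-08) and Cldn7, a claudin (-8.60, adjusted p = 1.45e-07), completed the largest differences. Of 14 epididymis and testis genes 13 were lower in BAT, also adjusted over the list alone (median -7.67, camera adjusted p = 6.02e-08, adjusted p = 0.23 with an estimated correlation), and in BAT of KO the same lipocalin was 5.68 ± 2.58. All 12 mesothelial genes were lower in BAT, among them Upk1b (-5.20) and the keratin Krt19 (-6.29), with a camera adjusted p of 5.17e-07 and adjusted p = 0.0163 with an estimated correlation. White adipocyte genes split 10 lower and 2 higher in BAT of 14 (the same adjusted over the list alone). Lower were the hormones leptin (-3.01) and resistin (-3.37) and angiotensinogen (-4.71, adjusted p = 1.54e-08), among others (camera adjusted p = 0.00044, adjusted p = 0.23 with an estimated correlation).

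Other groups separated the tissues of WT less widely. Of 20 macrophage genes 15 were lower in BAT, such as Ctss, a cathepsin (-2.32, adjusted p = 7.58e-07), and Lgals3, a galectin (-2.33, adjusted p = 3.73e-06). Of 18 matrix genes 14 were lower and 1 higher, of 19 cell cycle genes 14 were lower, and all 23 ribosomal protein genes were lower. The medians of these 4 lists were -1.36, -0.98, -0.83 and -0.77. Camera adjusted p were 5.91e-05, 0.000551, 0.00171 and 4.1e-08 (adjusted p = 0.367, 0.412, 0.32 and 0.32 with an estimated correlation). Adjusted over the list alone 15 macrophage, 15 matrix, 15 cell cycle and 23 ribosomal protein genes were lower. Higher in BAT were 15 of 25 PPARγ adipocyte genes (3 lower), 14 of 18 lipogenesis genes (3 lower), 8 of 16 endothelial genes (1 lower), 5 of 9 Schwann cell and nerve genes (1 lower) and 3 of 4 erythroid genes, the same counts as adjusted over each list alone. Gpd1 (2.70, adjusted p = 7.47e-07), Elovl6 (1.62, adjusted p = 1.82e-07), the VEGF receptor Flt1 (1.35, adjusted p = 2.58e-05) and the glial S100b (2.71, adjusted p = 3.53e-08) are examples. Fads1, a fatty acid desaturase, was lower (-3.83, adjusted p = 1.18e-07), as was Mal (-4.46, adjusted p = 6.14e-06). Camera adjusted p were 0.000193, 0.00024, 0.00422, 0.0229 and 0.0232; with an estimated correlation adjusted p = 0.564 for the adipocyte and endothelial lists and 0.23 for the other 3. The cholesterol (0.465), lymphocyte (0.617), immediate early (0.86), interferon (0.17) and glucocorticoid (0.86) lists and the 2 clock lists (0.172 and 0.544) did not pass camera, adjusted p in parentheses. The lymphocyte median was -0.01 and its mean 0.01. Within them Egr2 was 4449 ± 429 in WAT and 62.5 ± 4.82 in BAT, and Lcn2 9777 ± 129 and 18.6 ± 2.40. Arntl was lower in BAT (-1.02, adjusted p = 0.00255) as was Bhlhe41 (-2.00, adjusted p = 0.000379), and Hlf (1.12, adjusted p = 4.74e-05) and Cry1 (0.54, adjusted p = 0.000421) were higher.

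Of 19933 genes 10084 differed between the tissues of WT, 4044 higher and 6040 lower in BAT (40.1% higher), 1125 and 2405 of them beyond 2-fold, and the arrays did not overlap in 12101 of all genes (10% by chance). Of the lists 17 passed camera, 10 up and 7 down, 19 passed fry and 1, mesothelium, held with an estimated correlation. The split depended on the scaling of arrays: the median log2 difference of all genes was -0.03 as deposited, 0.11 after quantile normalization and 0.28 after median centring, and the counts became 6318 higher and 4686 lower, and 9433 higher and 3831 lower. Directions of single genes are therefore relative to that shift. The Schwann cell list failed among the brighter genes (adjusted p = 0.179) and without BAT WT replicate 3 (0.0636), over a range of 5.6e-05 to 0.23, and the cell cycle list among the brighter genes (0.399).

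In KO animals BAT and WAT were nearer to each other for brown-fat genes. Ucp1 was 10864 ± 310.4 in BAT and 3222 ± 1064 in WAT (log2 difference 1.80, SE 0.17, adjusted p = 6.33e-06). Serpina12, an adipokine, had the largest difference upward in BAT (262 ± 50.4 against 13.7 ± 3.16, log2 difference 3.22, SE 0.40, adjusted p = 5.2e-05). Next came Elovl3 (3.20, adjusted p = 4.76e-06), Dio2 (3.19, adjusted p = 9.74e-06), Myh4 (3.18, adjusted p = 0.000428), Kng2, a kininogen (3.16, adjusted p = 3.26e-07), and Otop1, a proton channel (3.14, adjusted p = 4.43e-07). Downward they were Defb48 (-9.25, adjusted p = 1.57e-07), Slc38a5 (-8.96, adjusted p = 6.75e-08), Wfdc10 (-8.81, adjusted p = 1.77e-07), Teddm2 (-8.67, adjusted p = 1.57e-07), the epididymal glutathione peroxidase Gpx5 (-8.52, adjusted p = 2.13e-07) and Lcn9 (-8.46, adjusted p = 2.13e-07). The brown-fat list had 20 of 21 members higher in BAT (21 adjusted over the list alone) with a median of 2.59. The respiratory chain had 50 of 50 with 1.58, the TCA cycle 15 of 15 with 1.82, fatty acid oxidation 22 of 23 with 1.88 and skeletal muscle 21 of 22 with 2.46. These 4 counts were the same adjusted over the list alone. Camera gave adjusted p of 2.69e-14, 4.55e-28, 7.35e-12, 5.88e-13 and 1.29e-07; with an estimated correlation adjusted p = 0.187 for the first, 0.287 for the next 3 and 0.341 for muscle. The test of this change against WT is the difference of the genotype differences given above.

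Other groups were higher in WAT of KO. Lower in BAT were 12 of 12 mesothelial genes, 12 of 14 epididymis and testis genes, 16 of 20 macrophage genes, 13 of 18 matrix genes, 22 of 23 ribosomal protein genes, 11 of 18 interferon genes and 10 of 14 white adipocyte genes (12, 12, 17, 14, 23, 11 and 10 adjusted over the list alone). Camera adjusted p were 1.49e-08, 2.68e-08, 1.02e-05, 0.000133, 2.03e-08, 0.0107 and 9.77e-05, and only mesothelium held with an estimated correlation (adjusted p = 0.00715; 0.287 for epididymis and white adipocyte and 0.341 for the other 4). Without WAT KO replicate 3 the interferon list did not pass (adjusted p = 0.0618; range over its alternatives 0.000471 to 0.341). PPARγ adipocyte genes (12 higher and 3 lower of 25, camera adjusted p = 0.0107, adjusted p = 0.678 with an estimated correlation) were higher in BAT. So were lipogenesis genes (13 higher and 3 lower of 18, 0.000932, adjusted p = 0.334 with an estimated correlation), and the counts were the same adjusted over the list alone. The adipocyte call ended under quantile normalization (adjusted p = 0.138) and without WAT KO replicate 1 (0.0902) or 2 (0.0525), over a range of 3.73e-07 to 0.678. Camera adjusted p were 0.113 for endothelial, 0.0505 for Schwann cell, 0.0933 for erythroid, 0.0552 for cell cycle, 0.157 for immediate early, 0.675 for cholesterol, 0.506 for lymphocyte, 0.519 for glucocorticoid and 0.642 and 0.519 for the clock lists. Median and mean differed in sign for the E-box clock list (0.03 and -0.03), and cholesterol genes had a median of -0.04 while camera gave up. Upk1b (-4.42, adjusted p = 4.18e-08), Trim14 (-3.16, adjusted p = 6.75e-08), Irf7 (-1.29, adjusted p = 1.23e-05), Pdgfra (-2.20, adjusted p = 2.9e-06) and Nfil3 (0.96, adjusted p = 0.00169) are examples.

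In KO 9366 genes differed between the tissues, 4019 higher and 5347 lower in BAT (42.9% higher), 911 and 2010 of them beyond 2-fold, and the arrays did not overlap in 11082 of all genes (10% by chance). Of the lists 14 passed camera, 7 up and 7 down, 18 passed fry and 1 held with an estimated correlation. Quantile normalization gave 5849 higher and 4176 lower, and median centring 9313 higher and 3387 lower, with median differences of all genes of 0.10 and 0.28 against 0.01. Called in both genotypes were 2999 genes higher in BAT and 4815 lower, where independent calls would give 815 and 1620, and 14 and 11 genes were called in opposite directions.

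Whether WAT of KO lay nearer to BAT was asked by correlating, across genes, the difference KO minus WT in WAT with the difference BAT minus WAT in WT. Pearson's r was 0.574 with a covariance of 0.201. Both differences use the WT WAT arrays, and 100 simulations without any change showed what this sharing gives. The simulated r was 0.501 (0.471 to 0.532), but no tissue difference was simulated, so it is no baseline for the observed r. The simulated covariance was only 0.0171, so that 0.184 of the covariance remained. The 3 shared arrays cannot be split into parts of at least 2 each, so the remainder was not shown to be free of them. Against the tissue difference in KO, which shares the KO WAT arrays and is biased downward by them, r was 0.392. Without WAT KO replicate 3, r was 0.255, the covariance 0.0793 and the remainder, with the same simulated covariance subtracted, 0.0623. Ucp1 was 2554 and 2665 on the other 2 KO arrays. The tissue differences of WT and KO correlated with r = 0.951. Genes are not independent replicates, and no p-value is given for these correlations.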

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

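The tests of explanations in this part were chosen after the result was seen, while the splits of the arrays were planned. The genotype difference was unequal between the tissues for 118 genes at an adjusted p under 0.05 for the difference itself, and those of them named by the rule are given here. Those with a gain in WAT above that in BAT were Ucp1 (-7.14), Cidea (-5.56), Cox8b (-4.36), Fabp3 (-4.10), Cox7a1 (-3.73), BC018473 (-3.71), Elovl3 (-2.63), Pdk4 (-2.59), Hadhb (-1.68), Sucla2 (-1.39), Suclg1 (-0.99) and Slc27a2 (-0.97). Anxa8 (-2.64) and Rsad2 (-1.08) were negative through a loss in BAT. Cxcl14 (3.02), Fbp1 (3.12) and Abhd1 (1.47) were positive through a larger rise in BAT, and Klrb1c (4.44), Scube1 (4.37), Gm609 (3.97), 9230020A06Rik (3.20), Krt23 (3.09) and Trim12a (1.03) through a larger loss in WAT. Haus4 (2.83), Lrrc23 (1.40) and Cmbl (-1.27), chosen after their values were seen, also passed, with opposite directions in the 2 tissues. The median differences of the lists past the threshold were -1.29 for brown-fat genes, -0.86 for fatty acid oxidation, -0.75 for the TCA cycle, -0.55 for the respiratory chain, -1.97 for skeletal muscle, -0.31 for PPARγ adipocyte genes, -0.25 for endothelium, -0.20 for interferon response, 0.28 for cholesterol synthesis and 0.36 for cell cycle. With an estimated correlation only the brown-fat list held (adjusted p = 0.0332); the other 9 did not, at 0.247 to 0.585.

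Brown-fat genes were higher in the WAT arrays of KO, and so was the skeletal muscle list, which BAT arrays carried at high intensity, although limma called only 1 of its 22 members (15 and 14 from the authors' p-values on log and linear values) and it did not pass with an estimated correlation (adjusted p = 0.38) or with fry (0.235). BAT admixed to these WAT samples may be part of the pattern: the mean of the muscle genes in WAT of KO lay at 8.47% of the distance from WAT of WT to BAT of KO (median of 21 members), that of the brown-fat genes at 11.8% (17 of 21 members), each over the members with at least 50 units in BAT of KO and 4 times their level in WAT of WT, and 18 of the 21 muscle genes lay above all WT arrays. The share of the muscle genes was 2.85% even on the KO array with the lowest one. That value restates that the muscle genes were higher, so it is no separate test of a brown-fat programme with no admixed tissue. Nor does it tell which tissue, if any, was admixed. Against more adipocytes stood the adipocyte list, whose median difference of 0.43 (upper quartile 0.60) was far below the brown-fat median of 1.61. Whether a brown-fat programme was raised in WAT beyond any admixed BAT cannot be told apart from these arrays, since the share of the brown-fat genes was 0.757, 0.960 or 2.51 times that of the muscle genes, depending on which BAT array of KO was taken as the admixed tissue. Single brown-fat genes had unequal shares, such as 29.6% for Ucp1, 20.2% for Cidea, 9.88% for Dio2 and 8.97% for Slc27a2. Their quartiles were 10.5% and 14.6%, and why they differed was not tested. Subtracted from the 3 KO arrays were 5.68%, 7.73% and 12.6% of the BAT signal. These shares came from all 22 muscle genes, which varied between BAT arrays. After the subtraction 10 brown-fat genes were called instead of 14, with a median of 0.74 instead of 1.61. Ucp1 went from 7.15 to 6.79 and Cidea from 5.63 to 4.98, but Elovl3 from 3.89 to 1.87, Dio2 from 2.27 to 0.38 and Slc27a2 from 1.45 to 0.03.

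WAT of KO replicate 3 stood apart from the other 2 arrays of its group. A sample with less epididymis may explain this: 10 of 10 abundant epididymal genes were lower than on both other KO arrays (median log2 difference -1.81, 3.51-fold) and 25 of 25 adipocyte genes were higher than on both (median 0.98). A BAT sample under a wrong label is argued against by the same epididymal genes, which lay above the BAT arrays of KO by 6.83 on the log2 scale. No biological explanation was tested.

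Of the genes called in both tissues, 80 had the same direction, as the loss of Per2 acting alike in WAT and BAT would give, and as a strain background differing between KO and WT animals could give too. Neighbouring genes were counted because such a background may differ in chromosome segments: 4 pairs of shared genes lay within 5 tested genes of each other, against a median of 1 and a 95th percentile of 4 in 10000 random draws (permutation p = 0.0739), and a median of 2 and a 95th percentile of 5 in 1000 draws from genes called in 1 tissue. A segment carried along with the Per2 mutation is argued against only as the source of most shared genes, which lay on 18 chromosomes. Of the 80 tested genes nearest to Per2, 0 were shared, 2 were called in WAT and 2 in BAT. Whether such a segment holds a few shared genes cannot be told from 80 genes. The loss of Per2 and the background cannot be told apart, because the labels do not give the strain of either genotype and a difference in background would follow the genotype in every array.

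Other splits of the same arrays were fitted. For 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real split gave 482 genes in WAT (highest other split 9), 343 in BAT (16), 10084 between tissues in WT (0) and 9366 in KO (0), each the 1 largest of its 10. For the lists it gave 15 in WAT (highest other 15, 2 splits as large), 5 in BAT (7, 3 splits), 17 between tissues in WT (16, 1 split) and 14 in KO (15, 4 splits). For the difference of differences 100 of 200 possible splits were fitted, and only 1, the real one, gave as many as 118 genes (highest other 79). The possible splits include ones that keep the real grouping in 1 tissue, and a mixed group of 3 still holds 2 arrays of 1 genotype. Real genotype differences can thus enter the counts of the other splits, which are not counts from chance alone. The splits test for no genotype difference in either tissue. They do not test whether the 2 genotype differences are equal, so chance was not excluded for unequal ones. As many as 10 lists came from 67 of the 100 splits (highest other 17), so chance was not excluded for the lists. Splits other than the real one thus passed up to 17 lists in camera at the preset correlation, so its adjusted p alone do not exclude chance for a list. Whether these lists passed through genes that vary together or through genotype differences left in the splits was not tested. With an estimated correlation only 1 of 24 lists passed between the tissues of WT, where fry passed 19. A list that failed with an estimated correlation is therefore not shown to be unchanged.

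Transcripts that name no single gene were not analysed further, although 55 of them, with 48 different sets of values, passed the threshold in both tissues.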

How the results depend on the processing

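All alternatives but the BAT subtraction and the count among genes under 2-fold between the tissues were planned; these 2 were chosen after the result was seen. In WAT the 482 genes became 127 with the 6 arrays alone, 755 with all transcripts tested by the authors, 1632 with array weights, 835 at an unadjusted p under 0.05 and 1.5-fold, 255 after subtraction and 144 among genes under 2-fold between the tissues, where fewer genes were tested. In BAT the 343 became 714 with array weights and 1071 or 1067 with the authors' p-values on log or linear values. The unadjusted threshold gave 6196 and 5437 genes between tissues in WT and KO. The 118 genes of the difference of differences became 73 among brighter genes, 440 with array weights and 796 at the unadjusted threshold. With an estimated correlation 1, 0, 1, 1 and 1 lists passed in the order WAT, BAT, tissues in WT, tissues in KO and difference of differences, and with fry 5 in WAT, 1 in BAT and 1 in the last. The correlation of the WAT difference with the tissue difference was 0.392 against the tissue difference in KO.

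Leaving out 1 array gave 225 to 871 genes in WAT, 165 to 238 in BAT, 8604 to 9391 between tissues in WT, 7865 to 9915 in KO and 59 to 372 for the difference of differences; 11 to 15, 5 to 6, 16 to 17, 13 to 16 and 9 to 15 lists; and a correlation of 0.255 to 0.646. Past 1.5 times were, in WAT, WT replicates 1, 2 and 3 (316, 254, 225) and KO replicate 3 (871); in BAT, WT replicates 2 and 3 (219, 223) and KO replicates 1, 2 and 3 (185, 179, 165); for the difference of differences, WAT WT replicates 1, 2 and 3 (73, 71, 59), WAT KO replicate 3 (372), BAT WT replicate 1 (76) and BAT KO replicates 1, 2 and 3 (65, 59, 68); and for the correlation WAT KO replicate 3 (0.255). The endothelial median in WAT reversed to -0.0724 without WAT KO replicate 3 and was 0.398 without WAT KO replicate 1. Of 4805 single values under all alternatives 4500 were the same, 250 lost their call, 54 gained it and 1 reversed.

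The replicate numbers are not stated to pair samples: over 18 pairings r was -0.12 to 0.0919 and 0 were over 0.1. In 7 of the 18 an array correlated best with the array of its own number in the other group. Only pairings of WAT with BAT of 1 genotype could join samples of 1 animal. Their r was -0.0373, -0.12 and 0.0607 in WT and 0.0147, 0.0746 and -0.0269 in KO. In each genotype 1 array correlated best with its own number. A replicate block gave 396 genes in WAT, 251 in BAT, 9717 and 8983 between tissues and 76 for the difference of differences. The cause was not tested for any of these shifts. Signal over background is not given per transcript in the sources used here, so a dim transcript was not told apart from an absent one.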

Other observations

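The shares of the distance to BAT and the genes named in this part outside their list's rule were chosen after the result was seen. Zic1 and Lhx8, 2 genes of the brown-fat list, were not called in WAT of KO. Their levels in BAT lay too near those in WAT for the missing calls to tell whether brown-fat transcripts were present. Zic1 was 121 ± 4.01 in WT and 128 ± 25.2 in KO (0.06, adjusted p = 0.928), against 223 ± 50.3 in BAT of WT, and Lhx8 was 238 ± 16.5 and 251 ± 26.1 (0.07, adjusted p = 0.862), against 265 ± 5.01 in BAT. Ebf2, an adipocyte transcription factor, was 75.7 ± 4.21 in WT and 164 ± 87.6 in KO (0.87, adjusted p = 0.094), against 387 ± 48.9 in BAT; it was not called either.

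Skeletal muscle genes varied between BAT arrays of 1 group. Their median intensities were 445, 814 and 1984 in BAT of WT and 305, 861 and 355 in BAT of KO, and Myh4 was 43.5, 172 and 126 on the WAT arrays of KO against 1.73 to 4.17 in WT. The median difference of muscle genes from WAT of WT on the 3 WAT arrays of KO, as a share of the distance from WAT of WT to BAT, was 2.85%, 14% and 8.92% against the mean of the BAT arrays of KO, and that of the brown-fat genes 8.50%, 9.42% and 18.3%. Against the BAT array of KO with the same number it was 5.54%, 7.76% and 12.6% for the muscle genes and 8.83%, 9.52% and 18.2% for the brown-fat genes. These shares cover 21 muscle and 17 brown-fat members, while the subtraction took its shares from all measured muscle genes.

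Epididymal transcripts were most intense in WAT: Defb48 was 40271 and 41111 on KO replicates 1 and 2 and 7933 on KO replicate 3. Per2 was 116, 108 and 172 on the WAT arrays of KO, 116, 99.5 and 122 in WAT of WT, 138, 151 and 158 in BAT of KO and 174, 158 and 163 in BAT of WT.

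The authors' own fold was 1.18 for Per2 in WAT and -1.11 in BAT, 532 for Ucp1 and 129 for Cidea in WAT.

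Of 7149 tested transcripts that name no single gene, 198 passed the threshold in WAT and 123 in BAT, and all 55 that passed in both had the same direction. These 55 hold only 48 different sets of values, so they are not 55 separate observations.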
